A study of Mus musculus with 4 samples.

How the data were processed

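RNA and TCR libraries were made from CD45-sorted leukocytes of B16 tumours, with 1 RNA and 1 TCR library from the pooled wild-type mice and 1 of each from the pooled mice labelled as Atpif1 knockout. Per the labels' protocols, tumours were digested, red cells were lysed, suspensions of the mice of a genotype were mixed and sorted, about 17400 cells were loaded per chip position, and libraries were made with the 10x Genomics 5′ V1.0 chemistry. The deposited RNA matrices hold UMI counts per gene and barcode that are neither normalised nor filtered for cells (737280 barcodes and 31053 genes each), made with Cell Ranger 3.1.0 per the file headers, on mm10 per the submitters' processing notes. The notes also name Seurat 3.2.0 and R 3.6.1 with no role given. The deposited TCR tables list contigs with counts of UMIs and reads, CDR3 sequences, V genes and marks for cells. Their assembly settings are not given in the sources used here. All further steps were computed from these counts.

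Barcodes were kept as cells with at least 1000 UMIs (5026 WT and 3610 KO), at least 500 genes (4730 and 3460) and at most 10% mitochondrial UMIs (4370 and 3211). Doublets were scored by an own implementation of the Scrublet scheme, simulated doublets against observed cells, and the highest-scoring cells were removed at 0.8% per 1000 barcodes, 153 (3.50%) in WT and 82 (2.55%) in KO. The 4217 and 3129 cells kept held 75.1% and 71.2% of all UMIs. Counts of both libraries were log-normalised and clustered together with the Leiden algorithm (2000 variable genes without TCR, immunoglobulin, mitochondrial and ribosomal genes, 30 components, 15 neighbours, resolution 1, no batch integration), and T and NK clusters were clustered again in the same way. Clusters were named from 22 marker lists by their score over detected markers (at least 3 markers at 50 CPM or more). Clusters whose leading genes held more markers of another type, or none of their own, stayed unnamed. A cluster mostly of 1 library may be that library and not a cell type.

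For each class UMIs were summed per library and divided by the class total to give CPM, with exact Poisson intervals. The log2 ratio of the library labelled KO over that labelled WT has the exact conditional binomial interval, and shares have exact Clopper-Pearson intervals, at the 95% level. All intervals and floors cover counting error only. With 1 pooled library per genotype no test between genotypes was possible, so no p-value and no count of changed genes is given. For each of 26 gene lists the median log2 ratio was taken over members with at least 20 UMIs summed over both libraries, with an interval from 1000 Poisson draws and a percentile among 10000 random lists of the same size matched on expression in 20 bins. Members at least 1.5-fold higher or lower were counted as a rule of size. A count of 0 was set to a floor of 3 counts for a bound on the fold, and the limit given for a share of 0 is 3 counts of the total, which for a gene limits cells with a UMI. Empty droplets were barcodes with 10 to 100 UMIs (61754 and 57860). Free RNA, estimated from haemoglobin and melanoma transcripts, made up 3.30% and 4.29% of the UMIs of T and NK cells. The estimate was 2.84% and 6.12% from the neutrophil genes S100a8 and S100a9.

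Genes were named by a rule of size. Genes with at least 50 UMIs and 20 CPM in a class, at a CPM above that of the same library's empty droplets, leaving out receptor segments, ribosomal protein genes and gene models with Gm, Rik or 2-letter clone names, were ranked by the bound of the interval nearest 0. The 10 highest and lowest are given for CD8 T cells and for monocytes or macrophages and the 4 highest and lowest for other classes, with Atpif1, members of the fixed lists and 8 genes given as shares after thinning each cell to 1000 UMIs. Named genes of B cells, neutrophils, plasmacytoid and migratory dendritic cells and unnamed clusters are not described here. Clonotypes were identical CDR3 nucleotide sequences of all productive, high-confidence TRA and TRB chains in cells kept with at least 1 of each. TRA or TRB contigs outside the T and NK clusters were not used. The number of gene names looked up in the RefSeq table of GRCm38 was 447, and coordinates come from that table for names with a single match. Aldoa, which had more than 1 identifier, was left out of the glycolysis list, and 37 of 38 complex I and 16 of 17 ATP synthase genes were found.

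The filters, clustering settings, marker lists, gene lists, naming rule and main alternatives were chosen before the data were examined. The thresholds for naming clusters and 9 further alternatives were chosen after. Alternatives changed the cell filters, the doublet removal, the cluster resolution, classes by gating on marker UMIs, the size factor, the depth, the free RNA, the UMI minimum of list members and the definition of a clone. The statistics were tested on Poisson counts simulated for both libraries from 1 pooled profile, with 200 changed genes. The intervals assume such counts, so this checks their computation only. It holds no variation between cells, mice or pools and no difference in the mix of cells. For CD8 T cells (4832 genes) 96.2% of intervals covered the true ratio and 90% of 2-fold and 100% of 4-fold changes were found in the right direction. For monocytes or macrophages (9694 genes) the values were 95.7%, 97% and 99%. Of the unchanged genes, 4.17% in CD8 T cells and 7.92% in monocytes or macrophages had intervals that excluded 0. The coverage allows for the shift that the changed genes give to the ratios of all genes, and these 2 percentages do not. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.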

Results

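Leukocytes were sorted by CD45 from B16 melanomas, tumours of a transplantable C57BL/6 mouse melanoma line, 12 days after injection into the flank of male mice. The mice were wild type (WT) or labelled as knockout (KO) for Atpif1, which encodes the inhibitory factor of the mitochondrial ATP synthase. Tumour suspensions of the mice of 1 genotype were mixed before sorting. The labels give a number of 6 mice, without saying whether per genotype. Each pool gave 1 droplet-based 5′ RNA library and 1 T cell receptor (TCR) library, so each genotype had 1 sample of each kind and no replicate. The WT library held 35152477 UMIs and the KO library 24385843. After filtering, 4217 WT and 3129 KO cells remained, with medians of 4186 and 4149 UMIs and of 1394 and 1470 genes per cell. With 1 pool per genotype no difference was tested and none has a replicate check. Intervals in parentheses are 95% intervals for counting error only, log2 ratios are KO over WT, and class names stand for cells that resembled the class by its markers.

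The first comparison was of the targeted gene, as a check of the labels. Atpif1 (ENSMUSG00000054428, GRCm38/mm10 chromosome 4, 132530555 to 132535450, RefSeq gene span) was not lower in the library labelled KO. Over all cells it stood at 582 CPM (573 to 592; 15373 UMIs) in the library labelled WT and at 682 CPM (670 to 695; 11840 UMIs) in the library labelled KO, a log2 ratio of 0.23 (0.19 to 0.26). These totals include melanoma cells of the injected line, which do not carry the genotype of the mice. There were 58 in WT and 17 in KO, with medians of 48534 and 26495 UMIs. In CD8 T cells Atpif1 was at 81.9 CPM (67.1 to 98.9) and 174 CPM (154 to 196), a log2 ratio of 1.09 (0.76 to 1.43). The log2 ratio was 0.52 (-0.19 to 1.28) in CD4 T cells, 0.14 (0.08 to 0.19) in monocytes or macrophages and 0.34 in type 1 conventional dendritic cells (cDC1), and -0.10 in plasmacytoid dendritic cells (pDC). Empty droplets held 537 and 577 CPM. The labels do not describe the allele, and a 5′ tag that lies outside the deleted part would be counted in both genotypes, so the level cannot check a deletion that leaves the tag in place. The direction of every comparison rests on the label alone.

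The second comparison asked how the leukocyte classes differed in share. Neutrophils made up 12.9% of the cells kept (11.9 to 13.9; 544 cells) in the library labelled WT and 0.991% (0.674 to 1.40; 31 cells) in the library labelled KO, 13.02-fold lower. Their log2 ratio was -3.70, and -2.83 with a minimum of 500 UMIs and 250 genes and -5.68 with one of 2000 UMIs and 800 genes. B cells made up 8.61% (7.78 to 9.50; 363 cells) and 1.37% (0.996 to 1.85; 43 cells), 6.26-fold lower. CD8 T cells were higher in the library labelled KO, at 11.3% (10.3 to 12.3; 475 cells) and 19.2% (17.8 to 20.6; 601 cells), as were CD4 T cells, at 2.04% and 5.40% (86 and 169 cells). Monocytes or macrophages were the largest class in both libraries, at 38.1% (36.6 to 39.6; 1607 cells) and 32.8% (31.1 to 34.4; 1025 cells). Among dendritic cells, which took 16.9% and 20.6%, cDC1, the subset that expresses Xcr1 and Clec9a, had a log2 ratio of 0.98 (0.68 to 1.29) and pDC one of -1.78. Regulatory T cells (44 and 49 cells; log2 ratio 0.59, -0.03 to 1.21) and NK cells (54 and 53 cells; 0.40, -0.17 to 0.98) did not differ beyond counting error.

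**Figure D1:**
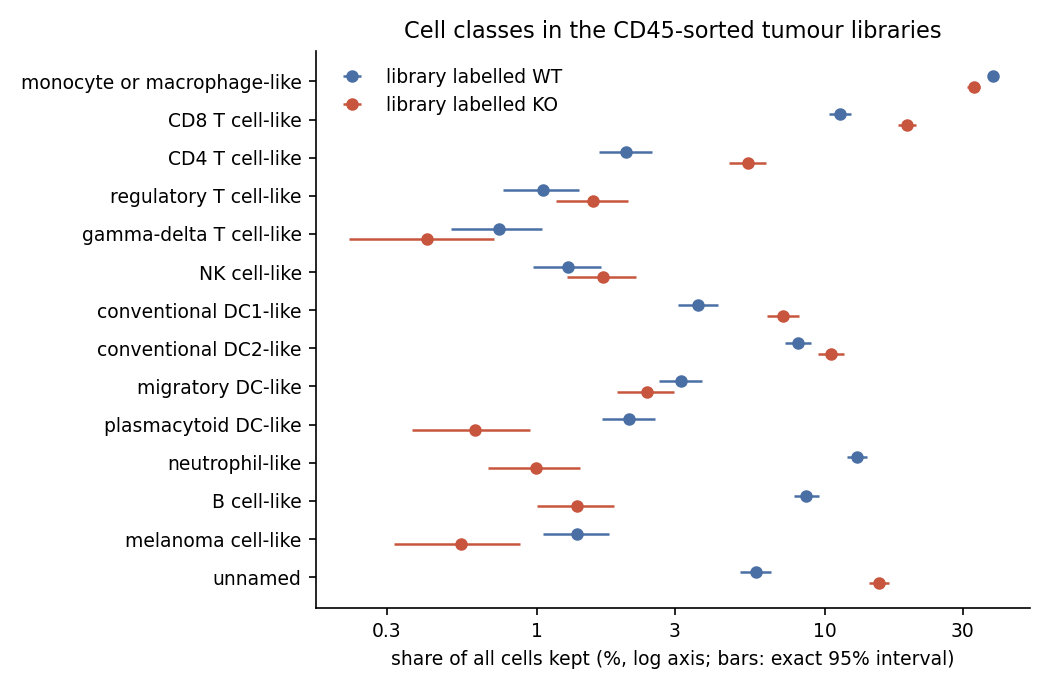
Share of the cells kept, in percent on a log axis, for each class in the library labelled WT (blue) and the library labelled KO (red). Points are shares and bars exact 95% Clopper-Pearson intervals for counting error. Neutrophils stood at 12.9% and 0.991% and CD8 T cells at 11.3% and 19.2%.

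The denominator set part of these values. Among T and NK cells (791 and 1045) the CD8 share was 60.1% and 57.5%, a log2 ratio of -0.06, and the CD4 share 10.9% and 16.2%. Among cells other than B cells and neutrophils (3310 and 3055) the CD8 share was 14.4% and 19.7% (log2 ratio 0.46), the dendritic cell ratio was -0.03, and the monocyte or macrophage ratio was -0.53. A stricter limit of 5% mitochondrial UMIs turned the monocyte or macrophage ratio to 0.24, and the addition of unnamed cluster 10 to the class turned it to 0.05. The CD45 sort and the UMI minimum also bear on shares. The median of neutrophils was 1752 and 1387 UMIs. Clusters left unnamed, under naming thresholds set after the data were seen, held 5.74% and 15.4% of the cells. They were cluster 10 (1.75% and 8.41%, leading genes Ear2, Retnla and Cxcl9), cluster 17 (1.59% and 1.89%, Gm26917 and Malat1), T sub-cluster 5 (2.09% and 3.04%, Ccl5 and Il2rb) and T sub-cluster 8 (0.308% and 2.08%, Hist1h2ap, Tnfrsf4 and Rgs16).

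The third comparison was of gene expression in CD8 T cells, the main class of the study's title (1307032 WT and 1564671 KO UMIs). Genes of inhibitory receptors and exhaustion were higher in the library labelled KO, with 13 of 16 measured members at least 1.5-fold higher and 0 lower and a median log2 ratio of 1.89 (1.56 to 2.17). Lag3, an inhibitory receptor that binds MHC class II (ENSMUSG00000030124, chromosome 6, 124904359 to 124912434), was at 3.83 CPM (1.24 to 8.93) in WT and 69.7 CPM (57.2 to 84.0) in KO cells, a log2 ratio of 4.19 (2.92 to 5.84). Tnfrsf9, the costimulatory receptor 4-1BB, had a log2 ratio of 3.08 (2.29 to 3.99), Rgs16 2.80 (2.27 to 3.38) and the inhibitory receptor gene Tigit 2.61 (1.85 to 3.46). With T sub-clusters 5 and 8 added to the class, Lag3 stood at 2.82, Tnfrsf9 at 1.45 and Tigit at 1.62. T cell cytokines and chemokines were also higher (8 of 12 members higher, 0 lower; median 1.16, 0.92 to 1.43), with Xcl1, the chemokine that attracts cDC1, at 2.61 (2.29 to 2.94), Lta at 2.35 and Il2 at 3.26 (1.25 to 6.39; 2 and 23 UMIs). Csf2 had 0 and 24 UMIs, at least 6.68-fold higher against a floor of 3 counts. Cytotoxicity genes had a median of 0.73 (0.52 to 0.90; 10 of 16 higher, 1 lower), with the granule protein gene Nkg7 at 1.28 (1.16 to 1.40), Fasl at 1.39 and Gzmk at 1.13, while the granzyme gene Gzma was lower at -1.73 (-2.60 to -0.93).

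The median of naive and memory T cell genes was lower, at -0.35 (-0.44 to -0.16), though only 3 of 15 members were at least 1.5-fold lower and 1 was higher. Satb1 stood at -0.84, the transcription factor gene Lef1 at -0.74 and the lymph node homing receptor gene Ccr7 at -0.61, which turned to 0.03 with sub-clusters given the same weights in both libraries. The median over all measured genes of the class was 0.18, and against 10000 random lists matched on expression the exhaustion, cytokine and cytotoxicity medians lay at the percentile of 100 and the naive and memory median at 0. The sub-clusters took different shares of the class in the 2 libraries. Sub-cluster 0 (leading genes Lef1, Satb1 and Tcf7) held 49.5% of the WT and 19.6% of the KO cells of the class. Sub-clusters 2 (Nkg7, Ccl5) and 4 (Ms4a4b, Cd8b1) held 13.3% and 12.4% of the WT cells and 27.6% and 22.3% of the KO cells. In an alternative chosen after the data were seen, 5 of the 6 sub-clusters (0, 2, 3, 4 and 9) were given the same weight in both libraries and sub-cluster 11, with 2 WT cells, was left out. The exhaustion median was then 0.82, the cytokine median 0.03, the cytotoxicity median 0.0017 and the naive and memory median 0.09. The sub-clusters were drawn from the same expression values, so these weights do not separate the mix from the expression. Without sub-cluster 11 but with no weights, the inhibitory receptors and exhaustion median was 1.60 and the cytokine median 0.58. Within sub-clusters the naive and memory median was 0.15 in 0, 0.19 in 3 and 0.16 in 4, against -0.27 in 2 and -0.10 in 9. Only the interval in sub-cluster 3 excluded 0.

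By the rule of size, the 10 genes highest in CD8 T cells of the library labelled KO also included Nrgn (ENSMUSG00000053310; chromosome 9, 37544493 to 37552745; 3 and 292 UMIs; log2 ratio 6.35, 4.78 to 8.63) and the chemokine gene Ccl1 (8 and 399 UMIs; 5.38, 4.39 to 6.60). Penk, which encodes proenkephalin, had 0 and 85 UMIs, at least 23.7-fold higher in the class as named. Igfbp7 had a ratio of 4.46, Nrn1 of 4.04 and Enpp2 of 3.80. Ccl1, Nrgn, Penk, Igfbp7, Xcl1 and Rgs16 were among the leading genes of sub-cluster 11, which held 2 WT cells and 31 KO cells and 13.7% of the KO UMIs of the class. Outside sub-cluster 11 the class held 2 WT and 2 KO UMIs of Ccl1 and 3 and 3 of Enpp2. On these few UMIs, in the weighted alternative that left sub-cluster 11 out, Ccl1 turned to -1.13 and Enpp2 to -1.18. The Penk fold depended on which cells were in the class. The unnamed T sub-cluster 8 held 83 WT and 36 KO UMIs of Penk (499 and 54.6 CPM, log2 ratio -3.19), and with sub-clusters 5 and 8 added to the class its ratio was 0.07. With classes gated on marker UMIs Penk turned to -1.08. The 10 lowest were Elovl6 (-1.89), Igtp (-1.61), Igfbp4 (-1.46), Irf4 (-1.73), Gbp5 (-1.74), Taf4b (-1.502), Fas (-1.52), Gzma, Zfp281 (-1.40) and the mitochondrial gene mt-Atp8 (-1.44, -1.65 to -1.23), whose sequence overlaps mt-Atp6, so that the counting of its tags is uncertain. Elovl6 and Igtp were among the leading genes of sub-cluster 0.

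**Figure D2:**
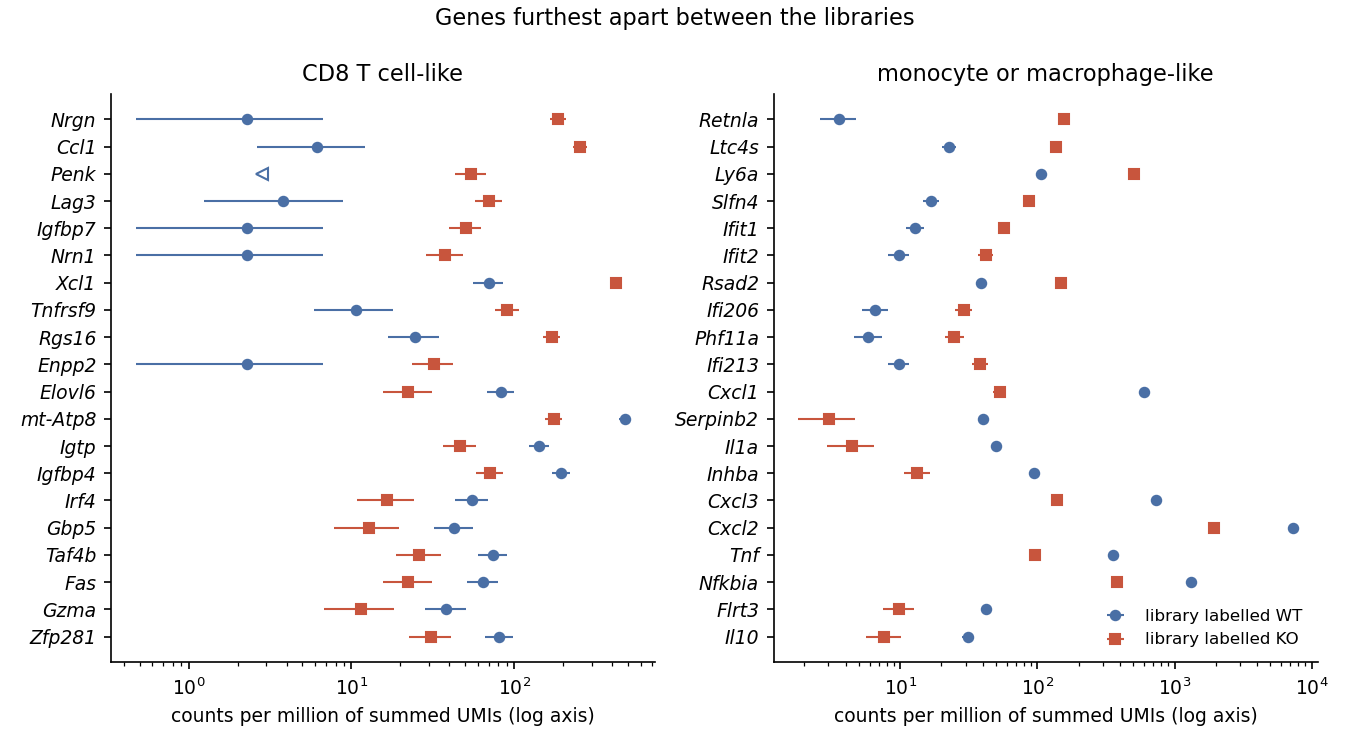
CPM of the summed UMIs (log axis) in the library labelled WT (blue circles) and the library labelled KO (red squares) for the 10 genes furthest apart in each direction in CD8 T cells and in monocytes or macrophages. Bars are exact 95% Poisson intervals for counting error. The open triangle is the upper bound of that interval for Penk, with 0 UMIs in WT. Retnla stood at 3.56 and 156 CPM and Lag3 at 3.83 and 69.7 CPM.

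The metabolic lists bear on the function of Atpif1. In CD8 T cells, nuclear genes of the respiratory chain and ATP synthase were higher in the library labelled KO by a small amount, and the interval of the glycolysis median included 0. The ATP synthase list had a median of 0.45 (0.31 to 0.48; 3 of 16 members at least 1.5-fold higher, 0 lower), with the subunit genes Atp5g3 at 0.70, Atp5j at 0.66 and Atp5e at 0.54. Complex I had a median of 0.49 (0.40 to 0.56; 11 of 37 higher, 0 lower), with Ndufb7 at 0.80 and Ndufa11 at 0.85, and complexes II to IV one of 0.45 (0.35 to 0.53; 8 of 25 higher, 0 lower), with Cox7c at 0.69. The TCA cycle median was 0.43 (0.17 to 0.55), the fatty acid oxidation median 0.24, the antioxidant median 0.04 and the median of mitochondrially encoded genes -0.02. Glycolysis and lactate genes had a median of -0.15 (-0.26 to 0.08; 0 of 19 higher, 1 lower), with Ldha, which makes lactate, at -0.35 and Gpi1 at -0.41. These medians stand against 0.18 for all genes of the class. With the same sub-cluster weights the ATP synthase median was 0.15, the complex I median 0.16 (1 of 37 higher), and the complexes II to IV median 0.13 (0 of 25 higher). The glycolysis median was -0.33 with these weights and 0.30 at the finer cluster resolution, so its direction depended on the setting. Ldha turned to between 0.04 and 0.13 under 4 of the cell filters or clusterings tried.

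The other lists in CD8 T cells differed in direction. Cell cycle genes were higher (median 0.74, 0.34 to 0.93; 10 of 16 higher, 1 lower), with the replication licensing genes Mcm3 at 1.24 and Mcm6 at 1.00, but the median was 0.26 with the same sub-cluster weights (1 of 13 higher, 1 lower). Both medians leave out the unnamed T sub-cluster 8, which held Cd8 transcripts and the highest Mki67 level of the T sub-clusters (285 CPM). MHC class I presentation had a median of 0.49 (0.34 to 0.57), with the immunoproteasome gene Psmb9 at 0.85, and 0.17 with the same sub-cluster weights (0 of 15 higher). Activation and costimulation genes had a median of 0.30 (5 of 18 higher, 2 lower), with Cd28 at 1.08 and Batf at -0.86. Interferon response genes had a median of -0.26 (-0.44 to -0.02; 5 of 26 higher, 7 lower), with Ifi27l2a at 1.32, Rtp4 at -1.26 and Iigp1 at -1.40. Without sub-cluster 0 this median turned to 0.19 and Iigp1 to 0.24. MHC class II presentation had -0.38 (-0.65 to -0.03), which turned to 0.34 without sub-cluster 9. Hypoxia response genes had -0.23, immediate early and dissociation stress genes -0.19 and ribosomal protein genes -0.16. Of the lists for other cell types, the inflammatory macrophage median was -0.46, the alternatively activated macrophage median -0.43, the complement and lipid-handling median -0.12 and the monocyte median 0.58. The melanoma and haemoglobin lists had fewer than 3 measured members.

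**Figure D3:**
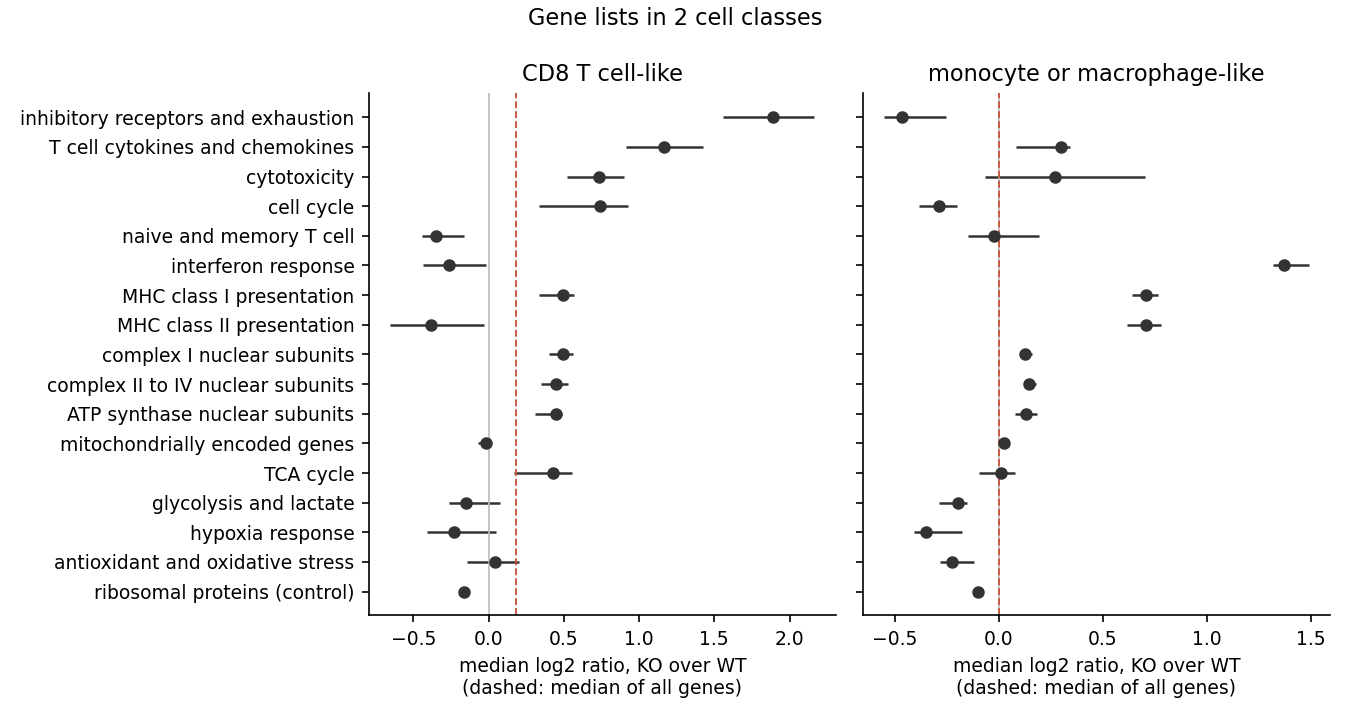
Median log2 ratio, KO over WT, of each gene list in CD8 T cells and in monocytes or macrophages. Bars are 95% intervals from Poisson resampling of the counts and the dashed line is the median over all genes of the class (0.18 in CD8 T cells). The exhaustion list stood at 1.89 in CD8 T cells and the interferon response list at 1.37 in monocytes or macrophages.

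Effector and memory genes were also compared as shares of CD8 T cells with a UMI, each cell thinned to 1000 UMIs (median depth 2523 and 2120 UMIs; no cell left out). Pdcd1, which encodes PD-1, was found in 1.89% of WT cells (0.870 to 3.57) and 6.32% of KO cells (4.51 to 8.58), and Lag3 in 0.421% and 4.66% (3.12 to 6.66). Ifng, the gene of interferon gamma, was found in 9.89% (7.36 to 12.9) and 14.6% (11.9 to 17.7), with intervals that overlapped. Tcf7, a transcription factor gene of naive and memory T cells, was found in 25.5% (21.6 to 29.6) and 18.1% (15.1 to 21.5). Gzmb stood at 1.26% (0.465 to 2.73) and 3.16% (1.91 to 4.89), Prf1 at 0.632% and 1.66%, and Mki67 at 0.421% and 0.499%. These shares do not cover the unnamed T sub-cluster 8 (13 WT and 65 KO cells). Over both libraries it held Cd8a and Cd8b1 at 567 CPM, Cd4 at 36.3 CPM and Mki67 at 285 CPM. In the sub-clusters of the CD8 T cell class Mki67 was at most 26.6 CPM. Havcr2 was found in 0 of 475 WT cells, which allows a share of cells with a UMI of up to 0.632%, and in 0.998% of KO cells. Without thinning the WT and KO shares were 3.79% and 14.5% for Pdcd1, 1.05% and 10.6% for Lag3, 14.3% and 22.96% for Ifng, 45.5% and 33.1% for Tcf7, 4% and 5.32% for Gzmb, 2.32% and 4.66% for Prf1, 0.421% and 3.16% for Havcr2, and 1.47% and 1.498% for Mki67. As background after thinning, the WT B cells (363 cells; median 1667 UMIs) had Lag3 and Prf1 in 0.551%, Havcr2 and Tcf7 in 0.275%, Mki67 in 0.826%, and Gzmb, Ifng and Pdcd1 in 0 cells, which allows up to 0.826%. Lag3, Prf1, Gzmb, Havcr2 and Mki67 in WT CD8 T cells were therefore not above the B cell share beyond counting error. Cycling B cells also express Mki67, so that its share there is no pure background. The 43 KO B cells had Gzmb and Ifng in 2.33% (0.0589 to 12.3) and the other 6 genes in 0 cells, which allows up to 6.98%. They were too few to set a background for the library labelled KO, and Gzmb in KO CD8 T cells lay within their interval. In 1025 KO monocytes or macrophages Gzmb and Prf1 were found in 0 cells (up to 0.293%), and Ifng, Pdcd1, Lag3 and Tcf7 in 0.0976% (0.00247 to 0.542). The KO CD8 T cell intervals of these 6 genes lay above those values, but Havcr2 (2.15%) and Mki67 (1.56%) did not. Havcr2 was found in 3.86% (2.97 to 4.92) of WT monocytes or macrophages, above the 0.275% of WT B cells. Its share in monocytes or macrophages is therefore no pure background and does not place Havcr2 in KO CD8 T cells at a background level. Gzmb in WT CD8 T cells also lay above WT monocytes or macrophages (0 of 1607 cells, up to 0.187%).

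The fourth comparison was of monocytes or macrophages (12937154 WT and 6319278 KO UMIs). Interferon response genes were higher in the library labelled KO, with all 30 measured members at least 1.5-fold higher and a median of 1.37 (1.32 to 1.49). Among them the T cell attracting chemokine gene Cxcl9 had a ratio of 3.43, Iigp1 3.01, Ifit1 2.15 (1.89 to 2.43) and Gbp2 2.11. Antigen presentation genes were higher too, MHC class I with a median of 0.71 (0.64 to 0.77; 10 of 15 higher; H2-Q7 at 1.66, Nlrc5 at 1.503) and MHC class II with 0.71 (0.62 to 0.78; 6 of 9 higher; H2-Eb1 at 0.86, H2-Ab1 at 0.85, H2-Aa at 0.77). Retnla, a secreted product of alternatively activated macrophages (ENSMUSG00000061100, chromosome 16, 48842609 to 48844461), went from 3.56 to 156 CPM, a ratio of 5.45 (5.03 to 5.91). Among the 10 lowest genes were those of the neutrophil attractants Cxcl1 (-3.49), Cxcl3 (-2.39) and Cxcl2 (ENSMUSG00000058427; chromosome 5, 90903899 to 90905938; 7246 to 1939 CPM; -1.90, -1.93 to -1.87).

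The other genes among the 10 highest were Ltc4s (2.60), Ly6a (2.26), Slfn4 (2.37), Ifit2 (2.11), Rsad2 (1.93), Ifi206 (2.15), Phf11a (2.08) and Ifi213 (1.96). The other genes among the 10 lowest were Serpinb2 (-3.75), Il1a (-3.49), Inhba (-2.83), Tnf (-1.89), Flrt3 (-2.10), Il10 (-2.04) and the NF-κB inhibitor gene Nfkbia (-1.79). The inflammatory macrophage list as a whole had a median of 0.04 (4 of 15 higher, 4 lower) and the alternatively activated list 0.14 (5 of 18 higher, 3 lower; Lyve1 at 3.26, Ccl24 at 1.58), which turned to -0.02 with clusters given the same weights in both libraries. The monocyte list had 0.05 (3 of 15 higher, 4 lower), with Ly6c2 at 1.16, Ms4a4c at 1.19 and Plac8 at 1.03. The clusters took different shares of the class, with 37.6% of the KO and 10.6% of the WT cells in cluster 2 (Rsad2, Ifit3 and Ms4a4c), and 22.3% of the WT and 11.4% of the KO cells in cluster 6 (Mmp12, Cxcl3 and Inhba). With clusters given the same weights in both libraries the interferon median was 0.49, the MHC class I median 0.38 (4 of 15 higher) and the MHC class II median 0.18. The clusters were drawn from the same expression values, so these weights do not separate the mix from the expression. MHC class II medians within clusters went both ways, at -0.34 (-0.39 to -0.27) in cluster 2, -0.14 in cluster 3 and -0.21 in cluster 6, against 1.2015 in cluster 4, 1.23 in cluster 12 and 0.13 in cluster 13.

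Over all monocytes or macrophages the hypoxia response median was lower (-0.35, -0.41 to -0.18; 0 of 14 higher, 3 lower), with Ndrg1 at -0.82, Adm at -1.002 and Egln3 at -0.66. It turned to 0.02 with clusters given the same weights in both libraries. Within clusters the medians went both ways. They were 0.70 (0.48 to 0.88) in cluster 2, 0.16 in 3, 0.17 in 4 and 0.70 (0.24 to 1.00) in 13, against -0.15 (-0.25 to -0.05) in 6 and -0.08 (-0.36 to 0.17) in 12. Glycolysis and lactate genes had -0.20 (-0.29 to -0.15; none of 21 past 1.5-fold), with Eno1 at -0.51, the glucose transporter gene Slc2a1 at -0.58 and Pkm at -0.40. Their median was -0.06 with clusters given the same weights in both libraries. Antioxidant genes had -0.23 (1 of 21 higher, 3 lower), with the cystine transporter gene Slc7a11 at -1.99 and Gsr at -0.96. Medians for complex I (0.13), complexes II to IV (0.14), ATP synthase (0.13), mitochondrially encoded genes (0.02), the TCA cycle (0.01) and fatty acid oxidation (-0.14) lay closer to 0, and mt-Atp8 stood at -1.24. Cell cycle genes had -0.29 (0.15 with clusters given the same weights in both libraries), complement and lipid-handling genes -0.18 (Ctsb at -0.39, Spp1 at -0.27), immediate early genes -0.06 (Egr1 at -1.26) and ribosomal protein genes -0.10. The T cell lists had medians of 0.27 for cytotoxicity, 0.30 for cytokines (-0.44 with members of at least 100 UMIs), -0.47 for exhaustion (0.03 with no UMI minimum and 0.5 added), -0.03 for naive and memory and 0.10 for activation genes. Melanoma transcripts had a median of -1.06 (0 of 7 higher, 5 lower). In empty droplets they stood at 1774 CPM in WT and 449 CPM in KO.

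Interferon response genes were compared across the classes. They were higher in the library labelled KO in CD4 T cells (median 1.13, 0.70 to 1.40; 11 of 15 higher, 0 lower), NK cells (0.76, 0.18 to 1.44; 4 of 5 higher, 1 lower), cDC1 (0.97, 0.76 to 1.16; 20 of 26 higher, 0 lower) and type 2 conventional dendritic cells (cDC2; 1.14, 1.02 to 1.29; 25 of 29 higher, 0 lower). In regulatory T cells the median was 0.50 (-0.07 to 0.78; 6 of 15 higher, 2 lower) and in CD8 T cells -0.26. MHC class I presentation had a median of 0.28 in CD4 T cells, 0.46 in regulatory T cells, 0.10 (-0.06 to 0.40) in NK cells, 0.38 in cDC1 and 0.77 in cDC2. Differences between classes were not tested, and the NK cell median turned to -0.06 at the finer cluster resolution.

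**Figure D4:**
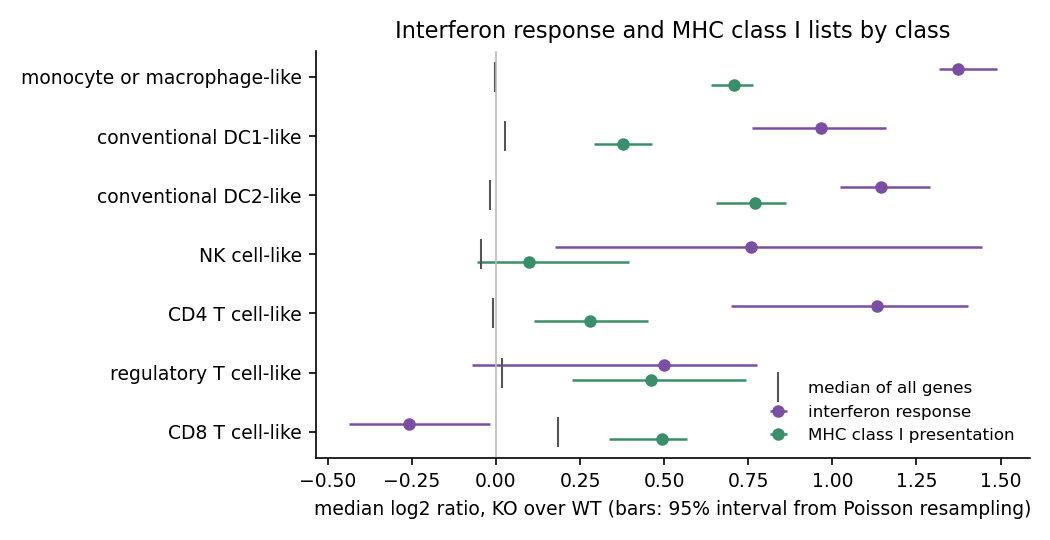
Median log2 ratio, KO over WT, of the interferon response list (purple) and the MHC class I presentation list (green) in each class, with 95% intervals from Poisson resampling of the counts; vertical ticks are the median over all genes of the class. The interferon response list stood at 1.37 in monocytes or macrophages, 1.13 in CD4 T cells and -0.26 in CD8 T cells, where it turned to 0.19 without sub-cluster 0.

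In CD4 T cells (203794 and 318794 UMIs) the 4 highest genes were the interferon-induced Ifit1 (1.83, 1.18 to 2.54) and Isg15 (1.22, 0.85 to 1.60), then Klf6 (0.98) and Ccdc117 (1.75). The 4 lowest were CAAA01147332.1 (-1.42), Batf (-1.22), Prr13 (-0.96) and Lsp1 (-0.92). Hypoxia response genes had a median of -0.65 (-0.92 to -0.21; 0 of 6 higher, 4 lower). In regulatory T cells (161812 and 205813 UMIs) the highest were Ifi27l2a (1.16, 0.96 to 1.36) and the proteasome genes Psme2 (1.07), Pomp (1.17) and Psmb10 (1.44). The lowest were Ccr7 (-2.61, -3.76 to -1.61), the apoptosis gene Pmaip1 (-1.53), Emb (-1.37) and Vgll4 (-1.56), and activation genes had a median of -0.20 (1 of 16 higher, 6 lower). In NK cells (167329 and 127078 UMIs) the highest were Id3 (1.92), Ly6c2 (0.92), Npm3 (1.10) and Gadd45g (1.13), and the lowest Rgcc (57 and 1 UMIs; -5.44, -10.76 to -2.90), Gzma (-3.19), mt-Atp8 (-2.04) and Fosb (-1.55). Immediate early and dissociation stress genes had a median of -0.55 in NK cells (0 of 18 higher, 6 lower) and cytotoxicity genes -0.06. Under gating on marker UMIs the NK cell immediate early median turned to 0.06 and Prr13, regulatory Ccr7 and Pmaip1, and NK cell Fosb, Id3, Gadd45g and Ly6c2 turned direction, and Gzma in NK cells turned to 0.13 at 5% mitochondrial UMIs.

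The last comparison was of TCR clones, to compare clonal expansion. Paired TRA and TRB chains were recovered from 83 of 706 αβ T cells of the library labelled WT (11.8%, 9.47 to 14.4) and 96 of 979 of the library labelled KO (9.81%, 8.02 to 11.8). Over all T and NK clusters 12 of 88 paired WT cells (13.6%, 7.25 to 22.6) and 47 of 98 paired KO cells (48.0%, 37.8 to 58.3) belonged to clones of 2 or more cells. These cells made 6 WT and 11 KO clones. A cell counts only if another sampled cell shares its clone. The intervals of all clone shares therefore treat cells that are not independent as independent, and they do not measure the counting error of these shares. Among CD8 T cells, with clone sizes counted within the class, the shares were 18.9% (9.44 to 32.0; 10 of 53) and 54% (39.3 to 68.2; 27 of 50). With sizes counted over all T cells, 42 of these WT cells and 21 of these KO cells were seen once. WT cells made 82 clonotypes with 0 clones of 3 or more, and KO cells 62 clonotypes with 10 such clones and a largest clone of 8 cells. With clonotypes by TRB alone (202 and 225 cells) there were 3 such clones in WT and 9 in KO, and the largest had 3 and 24 cells. Counted within T sub-cluster 8 alone, 14 of 28 paired KO cells and 0 of 4 paired WT cells (up to 75%) were in clones of 2 or more. Counted within each class, no clone of 2 or more was seen in CD4 T cells (0 of 10 and 0 of 5, which allows up to 30% and 60%) or regulatory T cells (0 of 13 and 0 of 10, up to 23.1% and 30%). No clonotype was shared between the libraries. Mice were mixed before sorting, so clones of 1 mouse could set these shares, and a clone cannot be placed in a mouse.

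**Figure D5:**
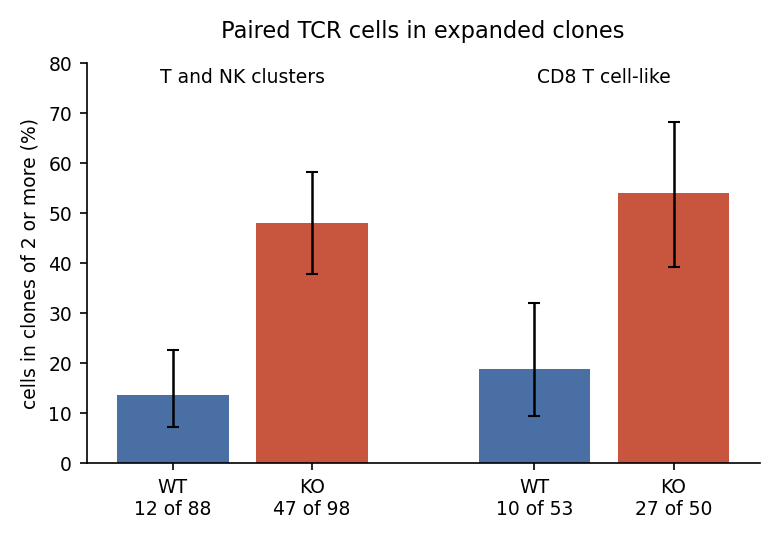
Share of cells with paired chains that belonged to clones of 2 or more cells, in percent, for each library over the T and NK clusters and over CD8 T cells. Clone sizes were counted within each of these sets of cells. Bars start at 0 and lines are exact 95% Clopper-Pearson intervals. Over the T and NK clusters the library labelled WT stood at 13.6% and the library labelled KO at 48.0%.

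With paired chains, expression by clone size could be compared only in the library labelled KO. Its 27 CD8 T cells of clones with 3 or more cells (9 clones, with sizes counted over all T cells; 138592 UMIs) were set against 21 CD8 T cells seen once (83689 UMIs). Cytotoxicity genes were higher in clones (median log2 ratio, clones over cells seen once, 1.36, 0.65 to 1.56; 5 of 7 higher, 0 lower), as were exhaustion genes (1.67, 1.25 to 2.35; 10 of 11 higher, 0 lower). Naive and memory genes were lower (-2.49, -3.32 to -1.57; 0 of 4 higher, 4 lower). The groups differed in sub-cluster, with 7 of the 27 and 1 of the 21 cells in sub-cluster 11. With sub-clusters 5 and 8 added (45 and 34 cells) the medians were 1.19 for cytotoxicity, 0.97 for exhaustion and -1.57 for naive and memory genes. Without sub-clusters 5 and 8 (27 and 21 cells), Nkg7 stood at 1.40 and Ifng at 3.56 (1.61 to 6.65; 39 and 2 UMIs). In the same cells Tcf7 stood at -2.43, against a median of 0.34 over all genes. Of 21 TRBV labels, among them the joint label TRBV12-2+TRBV13-2, 0 had an interval that excluded a log2 ratio of 0 when counted by clonotype.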

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

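The tests on Atpif1 and on neutrophils and B cells were chosen only after the results were seen, and the bounds for the exhaustion genes were written after their unweighted median and before the tested values were seen. The interferon response list stood apart between classes of the same libraries, with a median log2 ratio of -0.26 in CD8 T cells and 1.13 in CD4 T cells. In CD8 T cells the interferon response median was -0.01 with clusters weighted equally and turned to 0.0805 with a minimum of 500 UMIs and 250 genes, 0.12 with classes gated on marker UMIs and 0.19 without sub-cluster 0. The median was -0.40 (-0.72 to -0.04) in sub-cluster 0, 0.41 (-0.04 to 0.55) in 2, 0.64 (0.21 to 0.92) in 3, -0.28 (-0.56 to 0.10) in 4 and 0.40 (-0.12 to 0.73; 4 measured members) in 9. The difference between the classes was not tested. TCR contigs also appeared in data outside the T and NK clusters, where other kept cells with a contig that was not marked as a cell numbered 1124 in the library labelled WT and 459 in the library labelled KO.

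Atpif1 was not lower in the library labelled KO, with 582 and 682 CPM over all cells. Free RNA does not account for this, since the lower bound in CD8 T cells of the library labelled KO was 6.24 times the 24.7 CPM expected from free RNA. An exchange of the labels, with a deletion that removes the transcript, is argued against as well. In that case the library labelled WT would hold Atpif1 at the level of free RNA, and its lower bound was 32.3 times the 17.8 CPM expected. That total includes melanoma cells, but monocytes or macrophages of the library labelled WT alone held 645 CPM (631 to 659). A deletion that leaves the counted 5′ tags in place may still account for the level and stays open, because 0 of the UMIs have a position along the gene, as does an effect of the genotype on the remaining transcript, which was not tested.

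Exhaustion genes were higher in CD8 T cells of the library labelled KO, with a median log2 ratio of 1.89. Free RNA is argued against, since the median was 1.88 (1.57 to 2.22) after its subtraction. A different mix of sub-clusters cannot be told apart from a difference in expression. The median was 0.82 (0.54 to 1.18) with 5 sub-clusters given the same weight in both libraries, between the bounds of 0.5 and 1. The sub-clusters were drawn from the same expression values, so such weights can lower the median in either case. These weights also left out sub-cluster 11, without which the inhibitory receptors and exhaustion median was 1.60 in the unweighted class. Expanded clones cannot be told apart from the genotype with the few cells seen once (42 WT and 21 KO), whose median over 12 members was 0.57 (-0.12 to 1.02). That median took members with at least 5 UMIs, and the median of 1.89 those with at least 20, so the 2 are not over the same members. A biological effect of the genotype stays open and was not tested, since each genotype had 1 pool.

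Neutrophil and B cell shares were lower in the library labelled KO, with log2 ratios of -3.70 (-4.27 to -3.18) and -2.65 (-3.14 to -2.19). The UMI and gene minimum is argued against as the whole cause for neutrophils, since with 500 UMIs and 250 genes the ratio was -2.83 (-3.13 to -2.54). A single source of blood or lymphoid cells in the library labelled WT cannot be told apart from an effect of the genotype. If it had brought all naive-like CD8 T cells, their share would be lower by the same factor, whereas the log2 ratio of their sub-cluster 0 was -0.56 (-0.89 to -0.24), a difference of -3.14 from the neutrophil ratio. Part of these cells may have come from the tumours, however, so this excludes no such source. Haemoglobin transcripts in empty droplets went with a source of blood, with a log2 ratio of -4.64 (-5.29 to -4.06). Melanoma transcripts, which are not of blood, were also lower there, at -1.98 (-2.07 to -1.90). The ratios of -2.58 for S100a8 and S100a9 and -1.57 for Cd79a and Cd79b are of the same cells whose shares are to be explained and add no separate support. Separate sources in the pooled tumours, the handling of the suspensions and a biological effect of the genotype stay open and were not tested.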

How the results depend on the processing

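Some alternatives give clusters the same weight in both libraries, add or leave out a cluster or sub-cluster, or use another denominator for shares. These were chosen only after the data were seen. Under all alternatives run, the B cell ratio (-3.00 to -2.33), the neutrophil ratio (-5.68 to -2.83), the CD4 T cell ratio (0.57 to 1.61), the Atpif1 ratio (0.22 to 0.44), the exhaustion median of CD8 T cells (0.82 to 2.24) and the interferon median of monocytes or macrophages (0.49 to 1.48) kept their direction. The shares of cells in clones, among cells with paired chains or, by TRB alone, with a TRB chain, were 10.4% to 15.9% in WT and 41.5% to 48.0% in KO. All 20 clone values lay within the interval of the main one, which treats cells of 1 clone as independent. Some of these values could not or did not move, however. Equal draws took all 88 paired WT cells and, for CD8 T cells, all 50 paired KO cells. For CD8 T cells, amino acid sequences and barcodes marked as cells gave the same counts as the main definition. Of 2346 values under alternatives for the other results, 1714 stayed within the main value's interval, 591 moved beyond it in the same direction or without a call, and 41 turned direction. The cause was not tested, unless the alternative itself removes the cells or members named. Gating on marker UMIs gives no value for B cells, dendritic cells and neutrophils.

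Cell filters moved several values. A minimum of 500 UMIs and 250 genes gave share ratios of 0.96 for CD8 T cells and -2.83 for neutrophils, CD8 T cell medians of 0.48 for cytotoxicity, -0.46 for naive and memory, 0.0805 for interferon response and 0.0530 for MHC class II, and Gadd45g at -0.75 in NK cells. A minimum of 2000 UMIs and 800 genes gave share ratios of 0.52 for CD8 T cells, -0.50 for NK cells, -0.36 for monocytes or macrophages and -5.68 for neutrophils. It gave CD8 T cell medians of 0.35 for cytotoxicity, -0.86 for naive and memory and 0.49 for ATP synthase, Ldha at 0.12, and an MHC class II median of 0.54 in monocytes or macrophages. A limit of 5% mitochondrial UMIs gave share ratios of -0.48 for NK cells, 0.24 for monocytes or macrophages and 0.47 for dendritic cells. CD8 T cell medians were then 2.19 for exhaustion, -0.52 for naive and memory and 0.66 for MHC class II, with Ldha at 0.0427. In NK cells Gadd45g was at -0.32 and Gzma at 0.13, and the MHC class II median of monocytes or macrophages was 0.80. Without doublet removal the share ratios were -0.0856 for monocytes or macrophages and 0.48 for dendritic cells, the CD8 T cell medians -0.52 for naive and memory and 0.34 for MHC class II, Ldha 0.10, and the MHC class II median of monocytes or macrophages 0.92.

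Classes were also drawn in other ways. At cluster resolution 2.0 the share ratios were -0.36 for monocytes or macrophages and 0.46 for dendritic cells, the CD8 T cell medians 2.24 for exhaustion, -0.71 for naive and memory, 0.17 for MHC class II and 0.62 for ATP synthase, Ldha 0.13, and the NK cell interferon median -0.0615. Classes gated on marker UMIs gave share ratios of 1.07 for CD8 T cells and -0.57 for NK cells. Their CD8 T cell medians were 0.29 for cytotoxicity, 0.61 for cytokines, -0.58 for naive and memory and 0.12 for interferon response, with Penk at -1.08. Gating gave Prr13 at 0.18 in CD4 T cells, Ccr7 at 1.39 and Pmaip1 at 0.39 in regulatory T cells, and in NK cells an immediate early median of 0.0621, Fosb at 1.01, Gadd45g at -0.86, Id3 at -0.74 and Ly6c2 at -1.96. In gated monocytes or macrophages the medians were -0.90 for cytokines and -0.14 for alternatively activated genes.

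Leaving out CD8 sub-cluster 0 gave a share ratio of 1.44, medians of 0.33 for cytotoxicity, 0.82 for cytokines and 0.19 for interferon response, and Iigp1 at 0.24. Leaving out sub-cluster 9 gave an MHC class II median of 0.34, and leaving out sub-cluster 11 medians of 0.58 for cytokines and -0.15 for naive and memory. Adding T sub-clusters 5 and 8 gave medians of 0.34 for cytotoxicity, 1.38 for exhaustion, -0.56 for naive and memory and 0.30 for MHC class II. Adding cluster 10 to monocytes or macrophages gave a share ratio of 0.0463 and medians of 1.00 for MHC class II and -0.10 for alternatively activated genes. With clusters given the same weight in both libraries, which left out CD8 sub-cluster 11 for its 2 WT cells, the CD8 T cell medians were 0.0017 for cytotoxicity, 0.0322 for cytokines, 0.82 for exhaustion, 0.0874 for naive and memory, 0.15 for ATP synthase and 0.0426 for immediate early genes, with Ccl1 at -1.13, Ccr7 at 0.0287 and Enpp2 at -1.18. In monocytes or macrophages the medians were then 0.15 for cell cycle, 0.49 for interferon response, 0.18 for MHC class II, 0.0192 for hypoxia and -0.0198 for alternatively activated genes.

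As a share of cells other than B cells and neutrophils, the ratios were 0.46 for CD8 T cells, -0.53 for monocytes or macrophages and -0.0267 for dendritic cells. As a share of T and NK cells they were -0.0623 for CD8 T cells, 0.57 for CD4 T cells, -0.25 for regulatory T cells and -0.43 for NK cells. A median-of-ratios size factor gave CD8 T cell medians of -0.53 for naive and memory and 0.26 for ATP synthase. Thinning each cell to 1000 UMIs gave Atpif1 at 0.44 in all cells, CD8 T cell medians of 0.47 for cytokines and 1.43 for exhaustion, and medians of -0.54 for cytokines and 0.81 for MHC class II in monocytes or macrophages. Members with at least 100 UMIs gave cytokine medians of 0.91 in CD8 T cells and -0.44 in monocytes or macrophages. In monocytes or macrophages the cytokine median was -0.0680 with free RNA subtracted, and the exhaustion median was 0.0339 with no UMI minimum and 0.5 added to each sum. Depth limited what could be compared in classes with few cells in the library labelled KO, such as plasmacytoid dendritic cells (19 cells), neutrophils (31) and B cells (43).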

Other observations

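No test is reported here, and the values over every class, in empty droplets and of V genes by cell were chosen after the data were seen. In cDC1 the 4 highest genes were the interferon-induced GTPase gene Iigp1 (3.55, 2.12 to 5.47), Dopey2 (2.13), Qpct (2.19) and Usp18 (1.44), and the 4 lowest were Ifitm1 (-1.70, -1.88 to -1.53), Hist1h1d (-2.09), Hist1h2ap (-1.10) and Tubgcp2 (-1.71). In cDC2 the 4 highest were Batf2 (3.18, 2.04 to 4.56), the guanylate-binding protein gene Gbp2 (2.40), Ly6a (1.92) and Ifi205 (1.96), and the 4 lowest were Klk8 (-1.84), Alox5, which encodes 5-lipoxygenase (-1.64), Epop (-1.83) and Acp5 (-1.36). MHC class II presentation genes had medians of -0.01 in cDC1 and 0.08 in cDC2, and cytokine and chemokine genes one of -1.14 in cDC1, with 6 of 6 measured members at least 1.5-fold lower. Within CD8 T cells, interferon response genes had a median of -0.40 (-0.72 to -0.04) in sub-cluster 0 and 0.64 (0.21 to 0.92) in sub-cluster 3, and exhaustion genes one of 0.38 (-0.03 to 0.86) in sub-cluster 0, 0.83 (0.62 to 1.39) in 2, 0.39 (0.02 to 0.74) in 3, 0.36 (-0.22 to 1.38) in 4 and 0.87 (0.01 to 1.32) in 9. The exhaustion medians of sub-clusters 0, 4 and 9 rest on 3 measured members each.

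Over 9 classes, 2 genes were higher in all of them in the library labelled KO with intervals that excluded 0 and 7 were lower in all. Gm47283, a gene model, and B2m, the light chain of MHC class I, were higher. The lower genes were Cxcl2, Eef1a1, Ftl1, Nfkbia, Tpt1, Ubb and mt-Atp8. Cxcl2 had 7013 and 1081 CPM in empty droplets. Free RNA at the estimated share would give 232 and 46.4 CPM in T and NK cells, close to the 173 to 337 and 38.9 to 100.4 CPM of these classes, which leaves their own expression of it unknown. Gm47283 had log2 ratios of 1.81 to 5.64 (median 4.26, with counts of 0 at the floor) and mt-Atp8 of -2.04 to -0.67 (median -1.31), while mt-Atp6, which overlaps mt-Atp8, stood at -0.13 to 0.23. A difference of strain between the pools was not tested, since counts per gene hold no variants, and it stays open for these genes and for the other comparisons between the pools. In empty droplets Gm47283 had 8.24 and 50.1 CPM and mt-Atp8 311 and 242 CPM. Haemoglobin transcripts had 186 and 7.47 CPM there, S100a8 and S100a9 together 4869 and 813 CPM, Cd79a and Cd79b together 77.4 and 26.1 CPM, and Nkg7 60.7 and 256 CPM.

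Counted by cell, 3 of 21 TRBV labels had intervals that excluded a log2 ratio of 0. Cells of 1 clone share their V gene, so these intervals treat cells that are not independent as independent. The 19 KO cells with TRBV10 made 8 clonotypes, the 16 with TRBV29 made 4, and the 8 WT cells with TRBV13-3 made 7. By clonotype the intervals of all 3 included 0. TRBV10 took 4.55% of paired WT and 19.4% of paired KO cells (2.09, 0.50 to 4.11), TRBV29 4.55% and 16.3% (1.84), and TRBV13-3 9.09% and 1.02% (-3.16). Melanoma cells, which the CD45 sort should remove, made up 1.38% of WT and 0.543% of KO cells, and γδ T cells 0.735% and 0.415%.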
